A study of Mus musculus with 95 samples.

How the data were processed

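The series holds 95 bulk RNA-seq libraries from cortex, kidney, liver and WAT of mice in the TLS, control and time-0 groups, with 8 animals per group and the animal as the unit of replication. Per the labels, mice were perfused with PBS, RNA was purified with an RNeasy kit, polyadenylated libraries were made with NEBNext Ultra II reagents and sequenced on a NovaSeq instrument, and reads were aligned to mm10 (GRCm38) with STAR 2.7.10; DESeq2 and DESeq are named for later steps. The deposited table holds raw counts per gene and library, and the first line of the file carries the word corrected, whose meaning is not given in the sources used here. Its values are whole numbers that sum to between 4031533 and 29269511 per library, both in liver. The strand and the gene annotation used for counting are not given there either. The table has 55401 genes with 55291 distinct symbols; 53292 symbols are in GENCODE vM21, which was used for coordinates and gene types, and 1999 are not. The sex label stands under the tag for cell line and was checked against Xist and 4 Y-linked genes. All 95 libraries passed this check, and M and F are used here as the labels give them. The labels give the 3-month treatment as "Stim", read here as TLS from the series title.

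Differences were tested with edgeR 4.0.16 in R 4.3.3, separately in each tissue. Genes were kept by filterByExpr with a minimum count of 10 on the treatment groups, libraries were scaled by TMM, and robust quasi-likelihood fits held all 3 groups of the tissue and sex as a covariate. The contrasts were TLS against control, control against time-0, TLS against time-0, and the difference of the TLS effect between M and F. The difference of the TLS effect between tissues was tested in a joint fit of all tissues. The same animals gave all 4 tissues, so this edgeR fit was repeated with the animal as a replicate block. It gave 263 calls with the block (214 shared) and 494 without it. A limma 3.58.1 fit without the block gave 473 (258 shared). Deviations of libraries were also compared across tissues. In 93 pairs of libraries from the same animal their mean correlation was 0.0462, against -0.0142 in 279 pairs from other animals of the same group and sex. The deviations were centred within each tissue, group and sex, which ties the second mean to the first. TLS animals A5DA (0.267) and 47BE (0.183) had the highest means and TLS animal E46E the next (0.0618). A swapped animal label could therefore go unseen. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested in the contrast. The SE of a log2 fold change is its size divided by the square root of its quasi-likelihood F, and log2 CPM values use a prior count of 2 (0.5 as an alternative).

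Genes are named by rule: the 7 largest rises and falls among called genes with a mean log2 CPM of at least 0 for TLS against control, 4 for the other contrasts, 3 for the sex difference and the 6 smallest p values for the tissue difference. Up to 4 members with the smallest p are named from each list, and clock genes and a few genes of cold, feeding and activity are always looked up; a few genes that these rules name are not reported here. The 51 gene lists were written down before the counts were examined, from general knowledge of each tissue, including markers of tissues that dissection can carry over. Lists with at least 3 measured members were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts of list members are given as adjusted over all genes and as adjusted over the list alone.

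The relation between the 3-month change in controls and the TLS effect was computed over 36 splits of the control animals so that the differences share no library, with a jackknife over animals and 100 simulations without change. Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, no low-count filter, a stricter filter of 1 CPM in 8 libraries, no sex covariate, sex crossed with treatment, and only the 2 groups compared. Each TLS and control library was left out in turn for TLS against control and the sex difference, and each TLS and control animal for the tissue difference; time-0 libraries were not left out in turn. In kidney, Xist and Y-linked genes fitted the labels, but time-0 animals 4 and 5 carry another letter in kidney than in the other tissues, so their exchange was tried. Since the labels fitted, the exchanged fit carries wrong letters and says nothing about how stable the counts are. Groupings were redrawn within sex, 40 times per tissue and contrast, 25 times for the tissue difference and 100 times for the list counts. Single libraries standing apart within a group were sought with Dixon's gap test at a chance level of 0.05 over 142 groups. Duplicated libraries were sought in 329 pairs by chi-square over genes with at least 20 counts per pair, and the lowest mean was 6.84.

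The method was tested on simulated data with the depth and spread of each tissue. In these data 200 genes with a mean of at least 1 CPM were changed, 100 by 2-fold and 100 by 4-fold. Genes were drawn independently, with no sex effect and no animal standing apart, so recovery in real libraries can be lower. The method recovered 94% and 100% of the changed genes in cortex, 78% and 99% in kidney, 53% and 95% in liver and 65% and 86% in WAT, with 4, 6, 12 and 11 false calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Per the labels, 1 batch code covers every library, so no batch comparison was possible, and the WAT library of control animal 9BA4 was not analysed here. Blood methylation and physiology were not analysed here.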

Results

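Polyadenylated RNA was sequenced from 4 tissues of C57BL/6J mice, the standard inbred laboratory strain, in 3 groups. Mice of the first group spent 3 months in a torpor-like state (TLS), control mice were kept for the same 3 months without it, and time-0 mice were taken at the start. Torpor is a natural state of lowered metabolic rate and body temperature that some mammals enter to save energy. The tissues were cortex, kidney, liver and white adipose tissue (WAT), the fat depot that stores lipid. Each group held 8 animals, 4 labelled F and 4 labelled M, so that each tissue had 24 libraries, except WAT with 23. The WAT library of control animal 9BA4 was not analysed here. The ages given with the counts were 205 days for TLS and control animals and 122 days for time-0 animals. The study's title names slower epigenetic aging of blood and a longer healthspan under TLS, and the expression data address what TLS changed in other tissues.

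The deposited values were raw counts of reads per gene. Total counts per library ran from 14299369 to 22962145 in cortex, from 8217875 to 28337864 in kidney, from 4031533 to 29269511 in liver and from 15881766 to 29089492 in WAT. Xist and Y-linked genes matched the F or M label in all 95 libraries, with 0 mismatches. No pair of libraries from the same group held identical values. The spread between animals differed by tissue: the common biological coefficient of variation was 0.144 in cortex, 0.268 in kidney, 0.377 in liver and 0.390 in WAT. A 2-fold change was simulated at these depths and spreads in genes of at least 1 CPM. It was called for 94% of changed genes in cortex (16609 genes tested), 78% in kidney (16005), 53% in liver (13604) and 65% in WAT (16784). The same effect is thus harder to see in liver and WAT. The library numbers in the labels ran from 50 to 96 for TLS and from 98 to 144 for control animals, so an effect of library order, if these numbers follow it, cannot be told apart from TLS. All 95 libraries carry the same batch code.

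The first comparison set TLS against control animals of the same age. In cortex, the largest named rises after TLS were in genes with immune roles. H2-Q7 and H2-Q6, class I histocompatibility genes that present peptides to lymphocytes, rose by log2 fold changes of 1.90 ± 0.34 and 1.74 ± 0.355 (SE; edgeR adjusted p = 0.00364 and 0.0089), and all 8 TLS libraries lay above the control mean of their sex. H2-Q7 averaged 4.57 ± 3.26 CPM (SD, n = 8) after TLS and 1.11 ± 0.561 CPM in controls (n = 8). The interferon-induced GTPases Iigp1, Gbp2 and Ifi47 rose by 1.92 ± 0.473, 1.88 ± 0.516 and 1.52 ± 0.447 (adjusted p = 0.0242, 0.039 and 0.0455), and Cd274, which encodes the checkpoint ligand PD-L1, rose by 1.62 ± 0.396 (0.0214). S100a9, a calcium-binding protein of neutrophils and other myeloid cells, had the largest log2 fold change of the named genes, 3.10 ± 0.775 (0.0264), from a mean of 0.392 ± 0.297 CPM to 3.93 ± 8.45 CPM (SD, n = 8).

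Over all called cortex genes, 46 fell and 38 rose by more than 2-fold. The 7 falls named by rule, which leaves out genes with a mean log2 CPM below 0, were smaller than the named rises and belonged to no common group. They were Bglap3 (-1.15 ± 0.344, adjusted p = 0.0474), Bdkrb2, the bradykinin B2 receptor (-1.10 ± 0.326, 0.0451), Trim71 (-1.07 ± 0.249, 0.0149), Atp2c2, a calcium pump of the secretory pathway (-1.0 ± 0.24, 0.0177), mt-Co2 (-0.95 ± 0.266, 0.04), Muc3a (-0.92 ± 0.249, 0.036) and Stpg1 (-0.90 ± 0.175, 0.00603). In Stpg1, Atp2c2, Trim71, Bdkrb2 and Bglap3, 0 of 8 TLS libraries lay above the control mean of their sex. On GRCm38, the H2-Q7 gene spans 35439155 to 35443773 and H2-Q6 spans 35424850 to 35430055 of chromosome 17, both on the + strand and protein coding, and reads of these close paralogs can be split by the counting. Iigp1 spans 60376027 to 60392634 of chromosome 18, Cd274 spans 29367455 to 29388095 of chromosome 19, and Stpg1 spans 135494790 to 135537803 of chromosome 4.

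Gene lists fixed in advance grouped these changes. Of 29 measured interferon response genes in cortex, 13 rose and 0 fell, among them Parp14 (0.97 ± 0.167), Trim30a (0.90 ± 0.191), Oasl2 (1.14 ± 0.261) and Gbp3 (1.30 ± 0.3). Of 16 antigen presentation genes, 9 rose, including B2m, the invariant chain of class I molecules (0.69 ± 0.14), H2-D1 (1.03 ± 0.207) and H2-K1 (0.84 ± 0.181). Of 18 markers of microglia, the resident macrophages of the brain, 10 rose, including Cx3cr1 (0.52 ± 0.103) and Tmem119 (0.35 ± 0.0779). Of 18 macrophage markers, 11 rose, including Cd84 (0.89 ± 0.148), Ctss (0.74 ± 0.139), Mpeg1 (0.57 ± 0.115) and Csf1r (0.41 ± 0.083). None of these lists had a member that fell. Adjusted over the list alone, 25 interferon, 13 antigen presentation, 15 microglia and 14 macrophage genes rose. As sets against all other genes, by camera, the adjusted p was 1.15e-13, 3.22e-08, 7.73e-13 and 4.71e-11, and the medians were 0.76, 0.79, 0.38 and 0.59. None of these calls held with an estimated correlation between genes: adjusted p = 0.347, 0.367, 0.259 and 0.347 with an estimated correlation.

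Some genes of the myelin and astrocyte lists rose as well. Of 20 genes of mature oligodendrocytes and myelin, the insulating sheath of axons, 6 rose and 0 fell, including Ugt8a (0.95 ± 0.142, adjusted p = 0.00163), Fa2h (0.57 ± 0.105) and Ermn (0.49 ± 0.123), and 15 did when adjusted over the list alone. The myelin set had a median of 0.43 and a camera adjusted p of 1.23e-09 (adjusted p = 0.367 with an estimated correlation). Of 16 astrocyte markers 5 rose, including the glutamate transporters Slc1a3 and Slc1a2 (0.36 ± 0.0825 and 0.35 ± 0.0836) and Acsbg1 (0.35 ± 0.0755), 7 when adjusted over the list alone (camera 3.3e-05; adjusted p = 0.367 with an estimated correlation). Gfap, the filament of reactive astrocytes, was at 0.31 ± 0.197 and was not called (adjusted p = 0.366). Enpp6 (0.69 ± 0.128) and Bcas1 (0.60 ± 0.172), genes of newly formed oligodendrocytes, were the 2 that rose of 18 precursor and newly formed oligodendrocyte genes, 2 when adjusted over the list alone, and that set was not called (camera 0.13).

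In cortex, 2 of 4 cold-inducible RNA-binding proteins fell. Cirbp (-0.34 ± 0.0852, adjusted p = 0.0228) and Rbm3 (-0.47 ± 0.126, 0.032) fell, 2 when adjusted over the list alone; both are induced in cells by mild cooling (camera 0.0235; adjusted p = 0.347 with an estimated correlation). TLS animal B23B stood apart on this list's score, at -0.395 with the nearest TLS library at -0.165. Of 16 glucocorticoid response genes, Sgk1 (0.90 ± 0.182, 0.0103) and Tsc22d3 (0.31 ± 0.0861, 0.0335) rose, 2 when adjusted over the list alone (camera 0.000701; adjusted p = 0.392 with an estimated correlation). Of 22 targets of ATF4, the transcription factor of the integrated stress response, Psat1 (0.28 ± 0.0654), Atf4 itself (0.21 ± 0.0552), Atf5 (0.23 ± 0.069) and 1 more rose while Nupr1 fell (-0.41 ± 0.115), against 7 and 1 when adjusted over the list alone (camera 0.00569; adjusted p = 0.367 with an estimated correlation). The 3 of 27 cell cycle genes that rose, Mki67 (1.21 ± 0.215), Ccnb1 (1.32 ± 0.348) and Top2a (1.02 ± 0.273), are markers of dividing cells and were low, with Mki67 at 2.01 ± 0.682 CPM after TLS and 0.863 ± 0.215 CPM in controls. In all 4 rose when adjusted over the list alone (camera 0.00312; adjusted p = 0.347 with an estimated correlation). The neuropeptide genes Npy (0.46 ± 0.0999), Vip (0.31 ± 0.0863) and Crh (0.45 ± 0.127) rose among 18 inhibitory neuron markers, with 5 up and 1 down when adjusted over the list alone (camera 0.0434; adjusted p = 0.367 with an estimated correlation). Of 29 immediate early genes, 16 excitatory neuron markers and 21 circadian clock genes, 0 were called (camera 0.704, 0.888 and 0.963), also when adjusted over the list alone; Fos was at 0.24 ± 0.387 and Arntl at 0.00 ± 0.0849.

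In all, 899 of 16609 genes were called in cortex, 497 higher and 402 lower, 84 of them by more than 2-fold, and 3745 had an unadjusted p below 0.05. Another measure moved with the groups beside every gene group named above, the share of counts from Malat1, Neat1 and Meg3, noncoding RNAs kept in the nucleus. Whether this share is technical or changes with the state of the animals was not tested. The share was 0.613 ± 0.0462% in M control libraries (SD, n = 4) and 0.311 ± 0.096% in F control libraries, against 0.268 ± 0.0475% and 0.273 ± 0.0441% in M and F TLS libraries. With this share as a covariate 2 genes were called; over the 899 genes the median size of the log2 fold change went from 0.358 to 0.23 and the median SE from 0.0886 to 0.102. F libraries alone gave 2 calls and M libraries alone 3404. All 14 genes named first lost their call in F libraries alone and with the covariate. DESeq2 called 1368 genes. Without TLS animal A5DA 451 were called and without TLS animal E46E 481. The count fell without each of the M control animals A367, 9BA4, E329 and 5A66, to 486, 366, 342 and 333. Without the F control animals 983B, A123, D215 and 9916 there were 748, 1188, 1374 and 771. Without A5DA the log2 fold change of S100a9 was 1.48 (adjusted p = 0.0849, with 0.00547 to 0.696 over 12 alternatives), and Gbp2 and Ifi47 missed the threshold (0.0645 and 0.0698), as did Muc3a (0.0695), mt-Co2 (0.0589), Bdkrb2 (0.0741), Bglap3 (0.0806), Rbm3 (0.0558), Atf4 (0.0661), Atf5 (0.0753), Tsc22d3 (0.0613), Vip (0.0791) and Crh (0.0642). Over the alternatives the adjusted p of Gbp2 ran from 0.00157 to 0.734, that of Ifi47 from 0.0136 to 0.724 and that of Rbm3 from 0.00525 to 0.487.

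**Figure D1:**
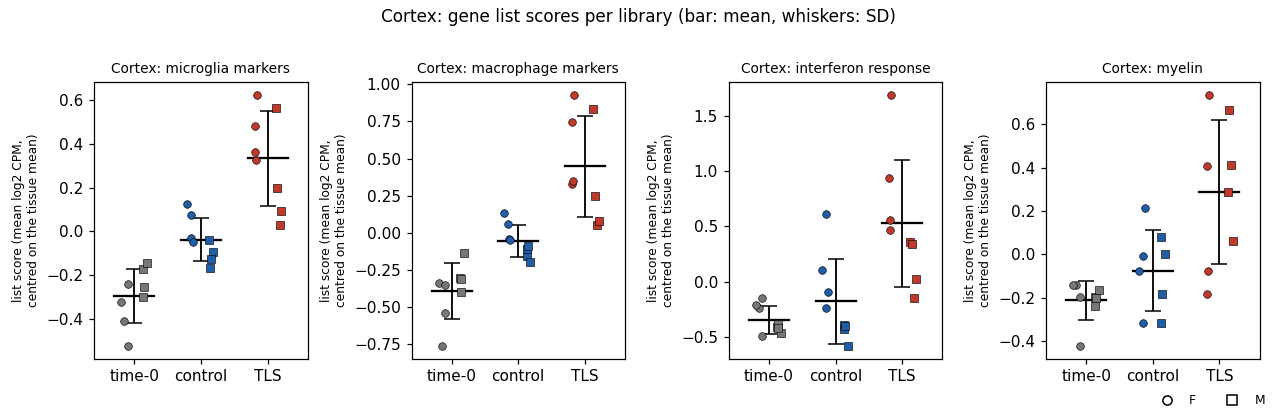
Scores of the microglia, macrophage, interferon and myelin lists in each cortex library (y axis, mean log2 CPM of the list's genes, centred on the mean of all cortex libraries), for time-0, control and TLS groups of 8 libraries; circles are F, squares are M, the bar is the mean and the whiskers the SD. The median log2 fold changes of TLS against control behind the panels were 0.38, 0.59, 0.76 and 0.43.

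**Figure D2:**
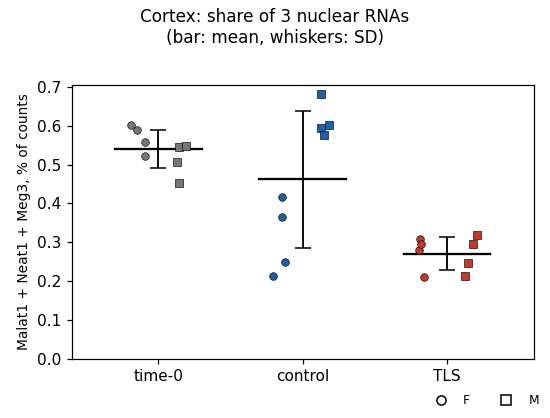
Percent of counts from Malat1, Neat1 and Meg3 in each cortex library (y axis, starting at 0), for time-0, control and TLS groups of 8; circles are F, squares are M, the bar is the mean and the whiskers the SD. The 4 M control libraries lie between 0.577 and 0.681%, the 4 F control libraries between 0.214 and 0.417%, and the 8 TLS libraries between 0.209 and 0.318%.

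In kidney, Igha and Jchain, genes of antibody-producing cells, fell. Igha, the heavy chain constant gene of immunoglobulin A, fell by 2.02 ± 0.251 on the log2 scale (edgeR adjusted p = 0.000106), from 39.2 ± 13.6 CPM in controls to 9.69 ± 3.28 CPM after TLS, close to the 9.89 ± 4.39 CPM of time-0 animals (SD, n = 8 each). Jchain, which joins immunoglobulin A chains, fell by 2.32 ± 0.368 (0.00243), while Pigr, the receptor that carries immunoglobulin A across epithelia, rose by 1.08 ± 0.155 (0.000849), from 137 ± 110 to 245 ± 161 CPM. Gfra1, a receptor for the growth factor GDNF, fell by 1.83 ± 0.185 (4.75e-06; 9.07 ± 4.39 to 2.46 ± 0.907 CPM), and Gpc3, a heparan sulphate proteoglycan of the cell surface, rose by 0.96 ± 0.11 (3.12e-05; 29.3 ± 2.74 to 56.8 ± 11.9 CPM). For each of these 5 genes either 8 of 8 or 0 of 8 TLS libraries lay above the control mean of their sex.

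Other named kidney genes rested on less. Scd1, the desaturase that makes monounsaturated fatty acids, fell (-1.54 ± 0.276, adjusted p = 0.0113), as did Ptpn5 (-2.41 ± 0.435, 0.0113), Anks1b (-1.67 ± 0.367, 0.0473) and Hes2 (-1.55 ± 0.32, 0.0341). Ubd, an interferon-induced ubiquitin-like gene, rose by 3.27 ± 0.646 (0.0293; 16.3 ± 28.0 against 1.48 ± 0.772 CPM), as did the antigen-loading genes H2-DMb2 (2.78 ± 0.586, 0.0428) and H2-DMb1 (1.22 ± 0.241, 0.0253) and Igfbp2 (1.95 ± 0.405, 0.037). Gc, the vitamin D binding protein, rose by less than these. Without TLS animal A5DA, H2-DMb2 was at 1.62 (0.0603, with 0.0179 to 0.919 over 13 alternatives) and Igfbp2 had an adjusted p of 0.0623 (0.00143 to 0.359 over 14). On GRCm38, Igha spans 113254830 to 113260236 of chromosome 12, Jchain 88519809 to 88527891 of chromosome 5, Pigr 130826684 to 130852249 of chromosome 1, Gfra1 58235604 to 58455909 of chromosome 19 and Gpc3 52272426 to 52613950 of chromosome X. Igha is annotated as an immunoglobulin constant gene and the others as protein coding.

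**Figure D3:**
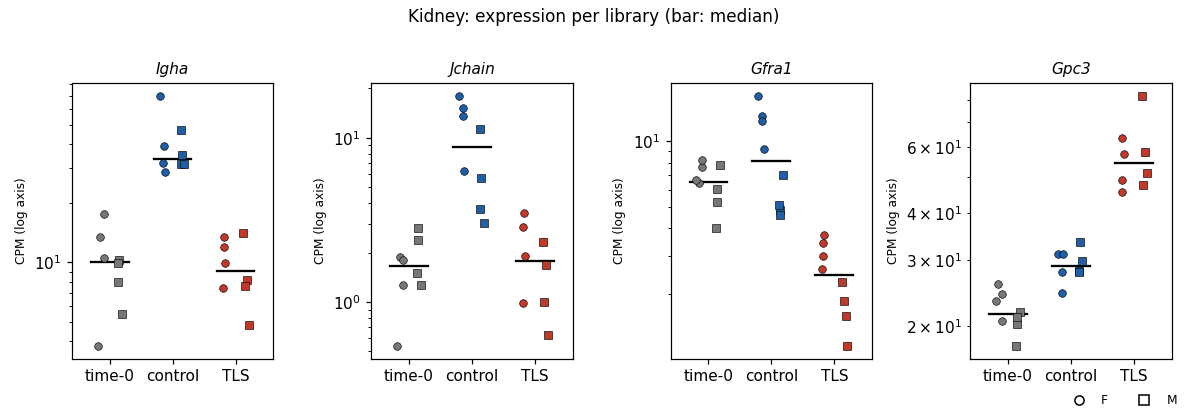
CPM of Igha, Jchain, Gfra1 and Gpc3 in each kidney library (y axes, log scale), for time-0, control and TLS groups of 8; circles are F, squares are M and the bar is the median. Mean CPM of Igha was 9.89 at time-0, 39.2 in controls and 9.69 after TLS, and mean CPM of Gpc3 was 21.9, 29.3 and 56.8.

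Among the kidney lists, members seldom passed one by one. Of 24 T and B lymphocyte markers only Jchain fell and 0 rose, 4 falling when adjusted over the list alone; Igkc (-1.63 ± 0.457) and Ighm (-1.05 ± 0.351) were not called. The signs differ for this list, with a median of 0.29, a mean of -0.17 and a downward test (camera 0.000257; adjusted p = 0.529 with an estimated correlation). Of 17 antigen presentation genes 1 rose and 0 fell, 14 rising when adjusted over the list alone (median 0.94; camera 2.84e-09; adjusted p = 0.39 with an estimated correlation). Of 17 glucocorticoid response genes 0 were called, against 8 up when adjusted over the list alone (median 0.53; camera 8.6e-07; adjusted p = 0.347 with an estimated correlation). Of 20 tubular injury and repair genes 0 were called and 14 were up when adjusted over the list alone. Havcr1, the injury marker KIM-1, was at 3.98 ± 1.04 (adjusted p = 0.161) and Krt20 at 3.11 ± 0.856 (0.187). TLS animal A5DA had a list score of 3.56 with the next library at 0.505 (camera 1.2e-05; adjusted p = 0.529 with an estimated correlation). Sets with 0 called members were shifted up for ribosomal proteins (48 measured, median 0.33, camera 6.02e-10, adjusted p = 0.575 with an estimated correlation) and cell cycle (31, 0.43, 1.94e-06; adjusted p = 0.367 with an estimated correlation). The same held for fatty acid oxidation (32, 0.22, 0.000208; adjusted p = 0.485 with an estimated correlation) and the interferon response (31, 0.32, 0.000529; adjusted p = 0.744 with an estimated correlation). The direction of fatty acid oxidation reversed in M libraries alone, and that of the interferon response without TLS animals A5DA and B4B9. Neither was called there. On the fatty acid oxidation score TLS animal B51B stood apart (0.993, nearest 0.302), and on the ribosomal score control animal E329 did (0.99, nearest 0.135). Mitochondrially encoded genes were shifted down (13, -0.34, 1.38e-05; adjusted p = 0.367 with an estimated correlation). Adjusted over the list alone, 0, 0, 4, 5 and 0 of these were called. Cirbp and Rbm3 were at 0.10 ± 0.146 and -0.29 ± 0.168 and were not called.

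In all, 37 of 16005 genes were called in kidney, 13 higher and 24 lower, 23 of them by more than 2-fold, against 1353 with an unadjusted p below 0.05. DESeq2 called 101 and limma with quality weights 398. With only the 2 groups compared 12 were called, without the sex covariate 7 and with the nuclear RNA share as a covariate 22. The count fell to 18, 19 and 22 without TLS animals B51B, B4B9 and 47BE, and to 17, 24, 20, 24, 20, 16 and 20 without control animals 983B, A367, A123, 9BA4, D215, 9916 and 5A66. Gfra1 and Gpc3 lost their call in 1 of 14 alternatives, M libraries alone, in which 0 genes were called.

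In liver, 5 of 24 fatty acid synthesis genes fell and 4 of 17 gluconeogenesis and fasting genes rose. Fasn and Acly, which make fatty acids and their acetyl-CoA precursor, fell (-1.95 ± 0.361 and -1.63 ± 0.279; edgeR adjusted p = 0.00518 and 0.00301). Fasn went from 1080 ± 528 to 254 ± 158 CPM, with 346 ± 126 CPM at time-0 (SD, n = 8 each). Thrsp (-2.23 ± 0.494) and Acss2 (-1.35 ± 0.314) were among the 5 of 24 fatty acid synthesis genes that fell, with 0 rising and 10 falling when adjusted over the list alone (median -0.45; camera 4.95e-08; adjusted p = 0.367 with an estimated correlation). Nsdhl (-1.43 ± 0.284), Sc5d (-0.80 ± 0.198) and Lss (-0.83 ± 0.21) fell among 25 cholesterol synthesis genes, 6 when adjusted over the list alone (camera 6.36e-10; adjusted p = 0.367 with an estimated correlation). Igfbp1, a binding protein of insulin-like growth factors that fasting induces (2.42 ± 0.549, 0.0232), Irs2 (1.45 ± 0.359), Pck1, the gatekeeper of gluconeogenesis (1.07 ± 0.284), and Foxo1 (0.68 ± 0.181) rose. They were the 4 of 17 gluconeogenesis and fasting genes that rose, with 0 falling and 5 rising when adjusted over the list alone (camera 0.0489; adjusted p = 0.53 with an estimated correlation).

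The largest named changes in liver were in other genes. Bhmt, which remethylates homocysteine, fell by 3.13 ± 0.433 (adjusted p = 0.000319), from 1759 ± 1115 to 208 ± 130 CPM (SD, n = 8 each). Tuba8, a tubulin gene, rose by 3.06 ± 0.318 (4.95e-06; 1.26 ± 0.409 to 10.6 ± 5.56 CPM), and Lrtm2 by 5.51 ± 0.636 (2.1e-05; 0.121 ± 0.205 to 4.84 ± 3.19 CPM), both in 8 of 8 TLS libraries. Sult1e1, the oestrogen sulphotransferase, rose by 4.77 ± 0.896 (0.00592), with 2.10 in F and 8.04 in M. Cfd, the complement factor adipsin of fat cells, fell by 6.09 ± 0.957 (0.00118), with 0.08 in F and -6.95 in M. Tafa2 (-3.72 ± 0.552, 0.000618), Cyp21a1 (-2.97 ± 0.52, 0.00352), the antisense transcript Hectd2os (-2.91 ± 0.396, 0.000319) and the paralogs Cyp3a44 (-3.55 ± 0.766, 0.0183) and Cyp3a41a (-3.43 ± 0.811, 0.0304) also fell. The strand of the counting is not given in the sources used here, so reads of Hectd2os and of the gene opposite it cannot be told apart, and reads of the Cyp3a paralogs can be split between them. On GRCm38, Bhmt spans 93616675 to 93637961 of chromosome 13, Tuba8 121210696 to 121226854 and Lrtm2 119315133 to 119330766 of chromosome 6, Fasn 120805846 to 120824547 of chromosome 11 and Sult1e1 87575969 to 87591594 of chromosome 5, all protein coding.

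**Figure D4:**
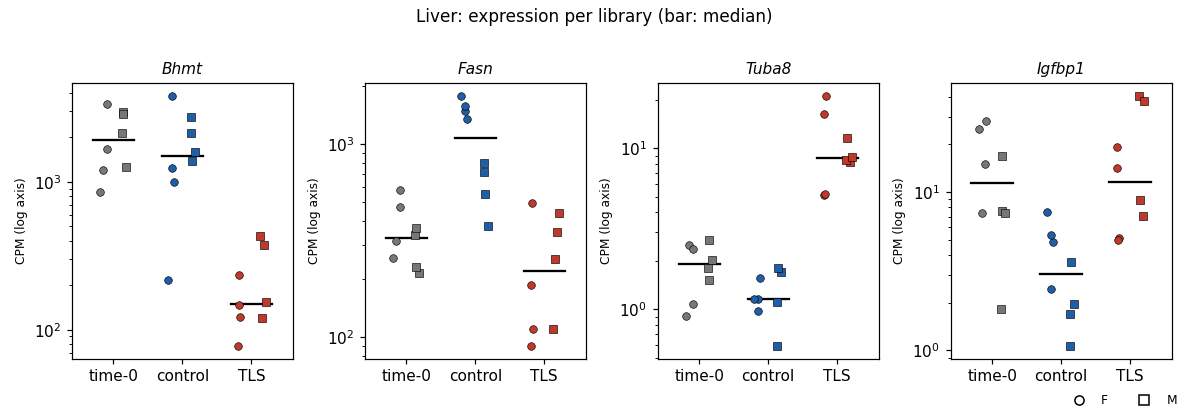
CPM of Bhmt, Fasn, Tuba8 and Igfbp1 in each liver library (y axes, log scale), for time-0, control and TLS groups of 8; circles are F, squares are M and the bar is the median. Mean CPM of Bhmt was 2043 at time-0, 1759 in controls and 208 after TLS, and mean CPM of Tuba8 was 1.87, 1.26 and 10.6.

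Some liver calls rested on TLS animal A5DA. Prtn3, a neutrophil protease (6.20 ± 1.57, adjusted p = 0.0445), and the metallothioneins Mt2 (5.92 ± 1.53, 0.0472) and Mt1 (4.65 ± 1.19, 0.0462) rose with it and were at 1.07 (0.335), 2.14 (0.104) and 1.69 (0.0693) without it; over the alternatives their adjusted p ran from 0.0454 to 0.409, 0.0287 to 0.577 and 5.52e-05 to 0.335. The citrate transporter gene Slc13a5 (4.46 ± 1.12, 0.0421) was at 1.78 without it (0.0431). Of 24 acute phase genes, which the liver secretes in inflammation, 4 rose and 0 fell, Hp (2.26 ± 0.506), Lbp (1.15 ± 0.307), Mt1 and Mt2, and 17 rose when adjusted over the list alone (median 1.27; camera 2.05e-06; adjusted p = 0.529 with an estimated correlation). Animal A5DA had a score of 4.89 and the next library 0.585, and Lbp missed the threshold without it (0.0532, with 0.00997 to 0.604 over 14 alternatives). Mt1 and Mt2 were also the 2 of 18 glucocorticoid response genes that rose, 3 when adjusted over the list alone (camera 0.00233; adjusted p = 0.367 with an estimated correlation). Of 26 xenobiotic and antioxidant genes, Ces2g (-1.07 ± 0.19), Aldh1a1 (-1.12 ± 0.245) and Gstm2 (-1.14 ± 0.272) fell and 0 rose, 6 falling when adjusted over the list alone (camera 3.05e-07; adjusted p = 0.367 with an estimated correlation); A5DA stood apart here too, at -2.25 with the next library at -0.559.

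Bile acid, sex-biased and clock genes were also measured in liver. Akr1d1 (-1.22 ± 0.242) and Baat (-0.76 ± 0.185), enzymes of bile acid synthesis and conjugation, fell among 15 genes, 4 when adjusted over the list alone, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.17 ± 0.34 (adjusted p = 0.0714; list by camera 0.00233; adjusted p = 0.367 with an estimated correlation). Of 25 female-biased genes 2 fell and 0 rose, against 8 and 1 when adjusted over the list alone (camera 2.05e-06; adjusted p = 0.367 with an estimated correlation). Of 21 male-biased genes Ugt2b38 rose (2.39 ± 0.546) and the major urinary protein genes Mup21 (-1.80 ± 0.41) and Mup12 (-2.30 ± 0.57) fell, against 4 up and 4 down when adjusted over the list alone (camera 0.157). Of 20 clock genes 0 rose and 1 fell, with 2 up and 2 down when adjusted over the list alone (camera 0.122). Of 48 oxidative phosphorylation genes Cox7b fell (-1.58 ± 0.341), and of 48 ribosomal protein genes 0 were called, 1 and 0 when adjusted over the list alone; both sets were shifted down (medians -0.47 and -0.46; camera 2.73e-09 and 3.58e-08; adjusted p = 0.461 and 0.577 with an estimated correlation). Col1a1 rose (1.29 ± 0.34) among 23 matrix genes, 6 when adjusted over the list alone (camera 2.28e-05; adjusted p = 0.367 with an estimated correlation). Igf1 (-0.20 ± 0.251), Fgf21 (0.50 ± 0.492), Cirbp (0.30 ± 0.202) and Rbm3 (-0.60 ± 0.226) were not called.

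In all, 265 of 13604 genes were called in liver, 93 higher and 172 lower, 181 of them by more than 2-fold, against 2383 with an unadjusted p below 0.05. DESeq2 called 620, limma with quality weights 1184 and edgeR with the nuclear RNA share as a covariate 449. With only the 2 groups compared 64 were called, without the sex covariate 154, in F libraries alone 2 and in M libraries alone 48. Without TLS animal A5DA there were 394 calls (219 shared). Without TLS animals B51B, B4B9 and E46E there were 137, 133 and 115 calls, without TLS animal B23B 803, and without control animals 983B, A367, 9BA4, E329 and 9916 there were 176, 94, 131, 165 and 84. Tuba8 was called in all 14 alternatives, with an adjusted p of at most 0.0467.

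In WAT, Serpina3k, a serine protease inhibitor gene, was the only gene called. It rose by 2.87 ± 0.453 on the log2 scale (edgeR adjusted p = 0.034), from 1.67 ± 0.72 CPM in controls (SD, n = 7) to 15.4 ± 14.3 CPM after TLS (n = 8), with 4.02 ± 2.51 CPM at time-0, in 8 of 8 TLS libraries. It spans 104338486 to 104346144 of chromosome 12 on GRCm38. Of 18 glucocorticoid response genes 0 were called and 5 were up when adjusted over the list alone, with Errfi1 at 1.09 ± 0.252, Pdk4 at 1.43 ± 0.367 and Fkbp5 at 1.12 ± 0.317 (median 0.46; camera 2.05e-06; adjusted p = 0.107 with an estimated correlation). Of 12 skeletal muscle markers, a check for carried-over tissue, 0 were called and 12 were up when adjusted over the list alone, with medians of 6.00 in F and 0.76 in M (camera 6e-06; adjusted p = 0.392 with an estimated correlation). Control animal A123 stood apart on that score (1.78, nearest -0.159). Antigen presentation (17 genes, median 0.61, camera 2.05e-06) and the interferon response (31, 0.48, 0.000119) were shifted up with 0 called members, 6 and 1 when adjusted over the list alone (adjusted p = 0.441 and 0.593 with an estimated correlation). The thermogenic list of brown and beige fat was shifted up (16 genes, median 0.39, camera 0.0219) and the adipocyte identity list down (21, -0.14, 0.0444), with 0 called members each, 4 and 0 when adjusted over the list alone (adjusted p = 0.401 and 0.764 with an estimated correlation). In F libraries alone the adipocyte identity list was called in the opposite direction, up. TLS animal A5DA stood apart on the adipocyte score, at -1.9 with the nearest TLS library at -0.274. Lep, the adipocyte hormone leptin, was at -0.97 ± 0.514 (adjusted p = 0.487).

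The count of 1 in WAT stood against 1857 genes with an unadjusted p below 0.05 and 176 called by DESeq2, while limma with quality weights called 0. It was also 0 without the sex covariate, with only the 2 groups compared and in F or M libraries alone, and 2 of 40 splits reached 1, so chance is not excluded. It was 3 without TLS animal A5DA and 2 without TLS animal E46E. It was 0 without TLS animals B51B and B4B9 and without control animals 983B, A367, A123, E329, 9916 and 5A66.

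**Figure D5:**
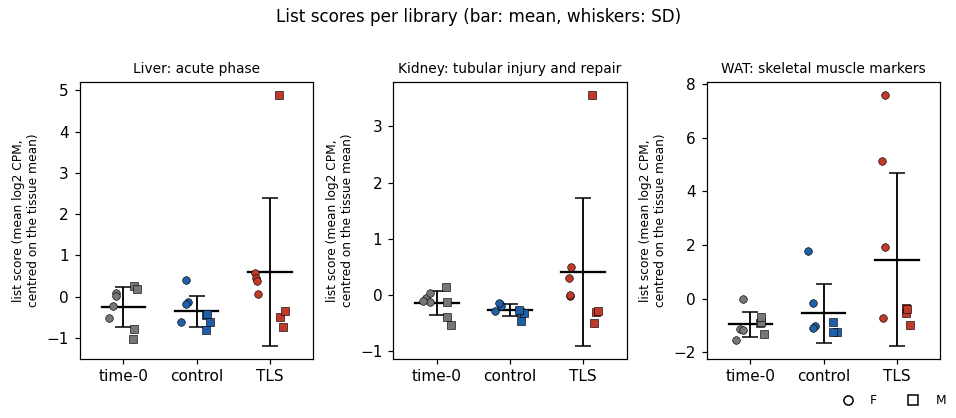
Scores of the acute phase list in liver, the tubular injury list in kidney and the skeletal muscle list in WAT for each library (y axes, mean log2 CPM of the list's genes, centred on the tissue mean), for time-0, control and TLS groups; circles are F, squares are M, the bar is the mean and the whiskers the SD. TLS animal A5DA lies at 4.89 in liver and 3.56 in kidney with the next TLS libraries at 0.585 and 0.505.

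Across the 107 list tests of TLS against control, 47 were called, 31 up and 16 down; with an estimated correlation 0 were, at adjusted p values of 0.107 and above, and fry called 12. As many lists were called in 43 of 100 splits of the samples, the real one included.

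The second comparison set control animals against time-0 animals, which were taken 3 months apart and differ in age, without TLS. Any other difference between the collections, such as hour of day or feeding, cannot be told apart from the 3 months. In F animals, time-0 libraries lay before control libraries in number (55 to 91 against 98 to 134 in cortex), whereas in M animals they alternated (103 to 139 and 102 to 138). The same held in liver and WAT and, but for 1 library of each sex, in kidney. If these numbers follow the order of the libraries, its effect cannot be told apart from the 3 months in F. F and M libraries alone gave 2965 and 1160 calls in cortex, 1964 and 0 in kidney, 1 and 6 in liver and 47 and 0 in WAT. In cortex, genes of protein synthesis and respiration rose and activity-induced genes fell. All 48 of 48 cytosolic ribosomal protein genes rose, also when adjusted over the list alone, with Rps14 at 0.74 ± 0.101 and Rpl18 at 0.58 ± 0.0847 (median 0.56; camera 4.76e-38; adjusted p = 0.686 with an estimated correlation). Of 48 nuclear-encoded oxidative phosphorylation genes 39 rose and 0 fell, 43 when adjusted over the list alone, including Ndufb9 (0.60 ± 0.099) and Cox4i1 (0.63 ± 0.107) (camera 3.61e-20; adjusted p = 0.686 with an estimated correlation). Of 29 immediate early genes, which neuronal activity induces, 16 fell and 0 rose, 20 when adjusted over the list alone (camera 6.89e-16; adjusted p = 0.686 with an estimated correlation). They were led by Nptx2 (-1.26 ± 0.092, edgeR adjusted p = 7.91e-10), Egr3 (-1.20 ± 0.101, 3.66e-08), Homer1 (-0.94 ± 0.0881) and Vgf (-0.69 ± 0.0731), with Fos at -1.12 ± 0.384 (0.0426). The largest named rises, Folr1 (2.06 ± 0.692), Trh (2.03 ± 0.647), Prr32 (2.0 ± 0.716) and Aqp1 (1.99 ± 0.646), include genes of the choroid plexus, the tissue that secretes cerebrospinal fluid. In all 6 of 14 choroid plexus markers rose, 8 when adjusted over the list alone (median 1.86; camera 1.2e-05; adjusted p = 0.686 with an estimated correlation). Choroid plexus lies outside the cortex, and tissue carried over at dissection could be the source of these marker rises, which was not tested. The largest named falls were Egr2 (-1.66 ± 0.43), Inhba (-1.35 ± 0.172), Slc23a3 (-1.33 ± 0.346) and Fosb (-1.31 ± 0.242).

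Further cortex groups changed over the 3 months. Cirbp (0.32 ± 0.0853) and Rbm3 (0.46 ± 0.126) rose, the 2 genes that fell in TLS against control. They averaged 77.7 ± 15.4 and 91.4 ± 16.7 CPM in controls against 61.9 ± 4.47 and 65.7 ± 8.88 CPM at time-0 and 61.2 ± 7.65 and 65.5 ± 16.4 CPM after TLS (SD, n = 8 each). Of 21 clock genes 6 rose and 5 fell, including Cry1 (0.41 ± 0.0842), Dbp (0.37 ± 0.0823) and Arntl (-0.60 ± 0.0843), with 7 and 5 when adjusted over the list alone (camera 0.966). Of 19 endoplasmic reticulum chaperones 9 fell and 1 rose, 11 and 1 when adjusted over the list alone (camera 0.000312; adjusted p = 0.686 with an estimated correlation). Of 20 heat shock genes 8 fell and 1 rose, 9 and 1 when adjusted over the list alone, with Hsph1 at -0.54 ± 0.0607 (camera 0.0045; adjusted p = 0.686 with an estimated correlation). Microglia markers rose in 6 of 18 cases and astrocyte markers in 7 of 16, with Gfap at 0.58 ± 0.198 and S100b at 0.47 ± 0.0904, 7 and 7 when adjusted over the list alone (camera 0.000335 and 0.000516; adjusted p = 0.686 and 0.686 with an estimated correlation). Excitatory neuron markers fell in 6 of 16 cases, 6 when adjusted over the list alone, with Tbr1 at -0.38 ± 0.0981 and Tle4 at -0.30 ± 0.0636 (camera 0.00273; adjusted p = 0.686 with an estimated correlation). In all, 3527 genes were called, 1789 higher and 1738 lower, 121 of them by more than 2-fold. The nuclear RNA share was 0.568 ± 0.0365% in F and 0.513 ± 0.0446% in M time-0 libraries (SD, n = 4 each).

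In kidney, immunoglobulin genes rose over the 3 months: Ighg2b by 5.07 ± 0.782 (edgeR adjusted p = 0.00265), Jchain by 2.42 ± 0.381 (0.00265), Igkc by 2.38 ± 0.477 (0.0328), Igha by 2.0 ± 0.253 (0.000203) and Ighm by 1.76 ± 0.366 (0.0386). Ighg2b, Jchain, Igkc and Ighm were the 4 of 24 T and B lymphocyte markers that rose, 6 when adjusted over the list alone (median 0.64; camera 1.73e-08; adjusted p = 0.686 with an estimated correlation). Of 21 clock genes 2 rose and 1 fell, among them Cry1 (1.75 ± 0.234, 0.000337) and Nr1d1 (-1.25 ± 0.258, 0.035), with 4 and 1 when adjusted over the list alone (camera 0.23). Acmsd, an enzyme of tryptophan breakdown, fell by 1.19 ± 0.14 (9.08e-05), and Adgrf1 (-2.34 ± 0.508) and Wnt9b (-1.11 ± 0.241) fell too. Phgdh (-0.78 ± 0.124) and Psat1 (-0.98 ± 0.19), enzymes of serine synthesis, fell among 21 ATF4 targets, 4 when adjusted over the list alone (camera 0.000185; adjusted p = 0.686 with an estimated correlation). The phosphate transporter gene Slc34a3 (-0.84 ± 0.154) fell among 20 proximal tubule genes, 5 when adjusted over the list alone (camera 0.000101; adjusted p = 0.686 with an estimated correlation). The count was 50 of 16005 genes, 22 higher and 28 lower, against 1804 with an unadjusted p below 0.05. It was 2515 by limma with quality weights, 2.2e+02 by DESeq2 (rounded to 2 digits) and 139 with only the 2 groups compared. Without the sex covariate there were 12.

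In liver, Nr1d1, the clock repressor REV-ERB alpha, fell by 2.16 ± 0.237 over the 3 months (edgeR adjusted p = 1.53e-05) and Bhlhe41 fell by 1.79 ± 0.405. Of 20 clock genes 1 rose and 2 fell, 2 and 4 when adjusted over the list alone (camera 0.317). Angptl8, a liver hormone gene that feeding induces, rose by 2.26 ± 0.412 (0.00532; 90.8 ± 64.4 to 439 ± 211 CPM, SD, n = 8 each), and Fasn rose by 1.58 ± 0.35 (0.0323). Of 24 fatty acid synthesis genes 2 rose and 0 fell, with 8 up when adjusted over the list alone (camera 8.01e-05; adjusted p = 0.686 with an estimated correlation). Irs2 (-1.98 ± 0.354) and Trib3 (-1.92 ± 0.294) fell. The remaining large changes were Slc2a4 (3.18 ± 0.542), Tnnc1 (2.66 ± 0.329), Lingo4 (2.23 ± 0.326), Derl3 (-2.31 ± 0.54) and Cyp4a31 (-2.26 ± 0.379). Ribosomal protein genes had 0 of 48 called and 20 up when adjusted over the list alone (median 0.65; camera 5.37e-16; adjusted p = 0.686 with an estimated correlation). The count was 72 of 13604, 29 higher and 43 lower, against 2057 with an unadjusted p below 0.05. DESeq2 called 247 and limma with quality weights 1397. There were 349 with only the 2 groups compared, 117 with the nuclear RNA share as a covariate and 39 without the sex covariate.

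In WAT, immunoglobulin genes led as in kidney: Igkv17-127 (7.08 ± 1.08), Igkv19-93 (5.76 ± 1.09), Ighv1-11 (5.32 ± 0.95), Ighg2c (5.28 ± 0.832, edgeR adjusted p = 0.00554) and Jchain (3.94 ± 0.754) rose. Of 30 T and B lymphocyte markers 2 rose, 9 when adjusted over the list alone (median 1.00; camera 6.61e-10; adjusted p = 0.686 with an estimated correlation). Variable genes such as Igkv17-127 belong to families of near-identical copies, so their counts are uncertain. Cry1 rose by 0.91 ± 0.152 (0.0117), and Cacna1g (-1.21 ± 0.228), Pim3 (-0.99 ± 0.2), Zfp703 (-0.73 ± 0.131) and Efnb1 (-0.63 ± 0.129) fell. Endoplasmic reticulum chaperones had 0 of 19 called and 12 down when adjusted over the list alone (median -0.46; camera 1.67e-08; adjusted p = 0.686 with an estimated correlation). The count was 27 of 16784, 22 higher and 5 lower, against 1953 with an unadjusted p below 0.05. DESeq2 called 210 and limma with quality weights 726, and there were 69 with only the 2 groups compared. The count was 62 without time-0 animal 6, 11 without the low-count filter and 6 without 4 libraries high in muscle genes. Across the tissues 38 of 107 list tests were called, 20 up and 18 down, 0 with an estimated correlation (adjusted p of 0.686 and above) and 7 by fry; 10 of 100 splits gave as many.

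The third comparison set TLS against time-0 animals and so holds the 3 months, TLS and any other difference between the collections. Here M libraries did not overlap in number (54 to 90 for TLS against 103 to 139 for time-0 in cortex), so library order cannot be told apart from this contrast in M. In cortex H2-Q7 rose by 3.46 ± 0.383 (edgeR adjusted p = 4.9e-07), S100a9 by 3.91 ± 0.823, H2-Q6 by 2.98 ± 0.388 and Ifi27l2a by 2.76 ± 0.438, and Slc23a3 (-1.93 ± 0.359), Nxf7 (-1.69 ± 0.264), Tnfrsf25 (-1.65 ± 0.227) and Egr2 (-1.65 ± 0.425) fell. In kidney Ubd (3.98 ± 0.679), Ighg2b (3.50 ± 0.804), Tgtp1 (3.15 ± 0.633) and H2-DMb2 (3.08 ± 0.594) rose, and Akr1c18 (-2.86 ± 0.556), Ptpn5 (-2.58 ± 0.427), Gfra1 (-1.47 ± 0.185, 0.000121) and Nr1d1 (-1.40 ± 0.257) fell. In liver Lrtm2 rose by 8.54 ± 0.803 (5.91e-07) from a time-0 level near 0 (0.00596 ± 0.0168 CPM), a fold that depends on the prior count. In the same tissue Sult1e1 (5.37 ± 0.898), Ighg2b (4.16 ± 0.783) and Ubd (3.64 ± 0.758) rose while Cfd (-4.22 ± 0.961) and the major urinary protein genes Mup15 (-4.05 ± 0.715), Mup9 (-3.96 ± 0.599) and Mup17 (-3.96 ± 0.826), a family of near-identical genes, fell. In WAT Ckm (8.63 ± 1.7), the creatine kinase of muscle, Chil3 (5.39 ± 0.99), Ighv1-11 (4.77 ± 0.922) and Apol11b (4.41 ± 0.933) rose, and Ccr3 (-2.59 ± 0.491), Thbs1 (-2.51 ± 0.47), Rps6kl1 (-1.36 ± 0.267) and Dusp8 (-1.26 ± 0.255) fell. Ckm stood at 843 and 121 CPM in TLS animals B51B and B4B9 against a control median of 0.0921, and muscle carried over with the tissue could be the source but is not settled. The counts were 5934 in cortex (3009 higher, 2925 lower; 807 with the nuclear RNA share as a covariate), and 109 in kidney (54 and 55; 408 by DESeq2, 43 with only the 2 groups compared, 20 without the sex covariate, 198 in F alone and 4 in M alone). They were 182 in liver (80 and 102; 457 by DESeq2, 100 without TLS animal B51B, 55 with only the 2 groups compared, 9 in F alone and 22 in M alone). Chance is not excluded for the liver count, since 3 of 40 splits reached it (highest other 235). In WAT there were 38 (27 and 11; 373 by DESeq2, 79 without TLS animal A5DA and 186 without time-0 animal 6). That count was 11 with only the 2 groups compared, 8 without the low-count filter, 6 without the 4 libraries high in muscle genes, 1 in F alone and 0 in M alone.

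Whether TLS moved genes against the change of the 3 months was asked by correlating the log2 fold changes of TLS against control with those of control against time-0 across all genes, with the control libraries split so that no library enters both differences. Genes are not independent replicates, so the error is a jackknife over animals. The split correlation was 0.00826 ± 0.121 in cortex, -0.0796 ± 0.134 in kidney, -0.279 ± 0.21 in liver and -0.157 ± 0.142 in WAT (mean of 36 splits ± SE), within 2 SE of 0 in each tissue. With all control libraries in both differences it was -0.138, -0.372, -0.506 and -0.428, where 100 simulations of unchanged groups sharing those controls gave -0.497, -0.502, -0.5 and -0.539. The covariance minus its simulated value was 0.00262, -0.00425, -0.0529 and -0.0175, beside jackknife errors of the split covariance of 0.0116, 0.0172, 0.0609 and 0.0352. No relation was therefore detectable beyond the spread between animals.

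The TLS effect was next compared between M and F animals. In cortex, 844 of 16609 genes had a TLS effect that differed (394 more positive in M and 450 more negative; 158 by more than 2-fold; 3730 with an unadjusted p below 0.05). Of the genes that the naming rule admits, Tdrd5 (1.75 ± 0.478, edgeR adjusted p = 0.0333), Plscr1 (1.69 ± 0.435, 0.0244) and the mitochondrial tRNA gene mt-Tt (1.55 ± 0.434, 0.0365) were the most positive. Isl1 (-3.60 ± 1.01, 0.043), a transcription factor of striatal neurons, Doc2g (-3.38 ± 0.963, 0.0489) and Slc10a4 (-3.38 ± 0.852, 0.0251) were the most negative; Isl1 was at 2.53 in F and -1.07 in M. The median TLS effect over 16 markers of the striatum and other neighbouring regions was 1.47 in F and -0.51 in M, and 0 of them were called for TLS against control, also when adjusted over the list alone (camera 0.0974). Between M and F animals, 1811 autosomal genes differed in control cortex, 51 in TLS cortex and 4 in time-0 cortex. With the nuclear RNA share as a covariate 21 genes were called (18 shared) and with the neighbouring-region score 3 (2 shared). Over the 844 genes the median size of the difference went from 0.59 to 0.51 and 0.491. Its median SE grew from 0.145 to 0.197 and 0.185. The nuclear RNA share moved with the difference, at 0.613 ± 0.0462% in M controls and 0.311 ± 0.096% in F controls (SD, n = 4 each). DESeq2 called 1331 genes, and 483, 1287, 523 and 543 were called without TLS animals DDF3, B4B9, E46E and 47BE, against 413, 426, 414, 355 and 541 without control animals A123, 9BA4, D215, E329 and 5A66.

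In liver, Cidec, a lipid droplet protein gene, was the 1 gene whose TLS effect differed (-5.46 ± 0.865, edgeR adjusted p = 0.0188; 0.88 in F and -4.59 in M), against 840 genes with an unadjusted p below 0.05 and 10 by DESeq2. Without TLS animal B23B the count was 1 as well, but of another gene (0 shared), so Cidec lost its call there. The count was 2 without TLS animals B4B9 and B03E and without control animal 983B, 3 without TLS animal A5DA, and 0 without TLS animal E46E and without control animals A367, A123 and D215. In kidney and WAT edgeR called 0 genes, with 1326 and 2563 at an unadjusted p below 0.05 and 2054 and 2 by limma with quality weights. DESeq2 called 16 in kidney and 2.2e+02 in WAT (rounded to 2 digits). In kidney 4 were called without TLS animal A5DA, 1 without TLS animal B03E and 1 without control animal A123, and in WAT 1 without each of the TLS animals B4B9, B23B and B03E.

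The TLS effect differed between the 4 tissues for 494 of 20294 genes by edgeR. It differed for 263 in edgeR with the animal as a block (214 shared) and for 473 in limma without the block (258 shared). Gfra1 had the smallest p value of the named genes (edgeR adjusted p = 7.47e-09), at -1.83 ± 0.193 in kidney, 0.76 ± 0.174 in liver, 0.20 ± 0.173 in cortex and -0.01 ± 0.213 in WAT. Lrtm2 (7.75e-09) was at 5.53 ± 0.505 in liver and between -0.15 and 0.04 elsewhere, and the ciliary transport gene Ift57 (4.84e-07) was at 1.60 ± 0.168 in liver. Tafa2 (8.45e-06) was at -3.69 ± 0.371 in liver, Tuba8 (7.09e-05) at 3.05 ± 0.37 in liver and 1.71 ± 0.395 in WAT, and Slc25a34 (0.000304) at 3.74 ± 0.452 in WAT. These p values come from the edgeR fit without the animal as a block. In the edgeR fit with the block the adjusted p was 5.07e-08 for Gfra1, 2.12e-06 for Lrtm2 and 3.11e-05 for Ift57. It was 1.77e-05 for Tafa2, 6.63e-05 for Tuba8 and 0.00223 for Slc25a34. The joint fit holds the same spread per gene in all tissues. The common coefficient of variation differed, at 0.144 in cortex, 0.377 in liver and 0.390 in WAT. In the fit of liver alone the errors of Tafa2 and Lrtm2 were larger, and Slc25a34 was not called in the fit of WAT alone. Without TLS animals A5DA, B23B and B4B9 there were 802, 1088 and 182 calls, and without control animals 5A66, 9916, 9BA4 and A367 there were 247, 222, 284 and 230. Few genes were called in the same direction in a pair of tissues. The histone genes H1f2 and H4c8 were higher in both cortex and liver, where 2.71 shared genes are the number for independent lists (415 × 79 / 12090), and Podxl2 was lower in both cortex and kidney, where that number is 0.396 (322 × 17 / 13827). Cortex and liver shared 0 lower genes against 2.14 for independent lists. These 3 genes were named after their values were seen.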

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

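The gap test for single libraries and the sex and tissue differences were fixed beforehand, but the list scores given to the gap test were chosen only after the result was seen, since they are those of the 47 lists called for TLS against control. Of 142 groups tested, 13 held a library that stood apart, where about 1 in 20, or 7.1, is the number by chance alone. TLS animal A5DA accounts for 6 of them. Its kidney library had a tubular injury score of 3.56 (nearest library 0.505), an ATF4 target score of 0.754 (0.178) and a nuclear RNA share of 0.959% (0.612%). Its liver library had an acute phase score of 4.89 (0.585) and a xenobiotic score of -2.25 (-0.559), and its WAT library an adipocyte score of -1.9 (-0.274). The other libraries standing apart in list scores were TLS animal B51B in kidney for fatty acid oxidation (0.993, nearest 0.302), TLS animal B23B in cortex for cold-inducible genes (-0.395, nearest -0.165), control animal E329 in kidney for ribosomal proteins (0.99, nearest 0.135) and control animal A123 in WAT for skeletal muscle (1.78, nearest -0.159). In composition, time-0 animal 8 in kidney and time-0 animal 1 in liver had 38.9% and 44.8% of counts in the top 20 genes (nearest 18.8% and 27.3%), and control animal E329 in liver had 9.84% mitochondrially encoded counts (nearest 5.23%).

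The TLS effect differed between M and F animals for 844 genes in cortex and 1 in liver. In cortex the largest named differences were Tdrd5 1.75, Plscr1 1.69 and mt-Tt 1.55 on the log2 scale, and Isl1 -3.60, Doc2g -3.38 and Slc10a4 -3.38; in liver it was Cidec at -5.46. In the edgeR fit without the animal as a block, the TLS effect differed between tissues for 494 genes. The edgeR adjusted p values of that fit were 7.47e-09 for Gfra1, 7.75e-09 for Lrtm2, 4.84e-07 for Ift57, 8.45e-06 for Tafa2, 7.09e-05 for Tuba8 and 0.000304 for Slc25a34.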

How the results depend on the processing

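Leaving out each TLS and control library in turn, for TLS against control and the sex difference, was fixed beforehand. So was leaving out each TLS and control animal for the tissue difference. Other runs without named animals, in F or M libraries alone and with covariates were chosen only after the results were seen. The remaining settings were fixed beforehand, and where a count moved the cause was not tested. Genes called for TLS against control, control against time-0, TLS against time-0 and the sex difference were 899, 3527, 5934 and 844 in cortex, 37, 50, 109 and 0 in kidney, 265, 72, 182 and 1 in liver, and 1, 27, 38 and 0 in WAT. With DESeq2 the TLS against control count was 1368 in cortex, 101 in kidney, 620 in liver and 176 in WAT. Control against time-0 gave 2.2e+02 in kidney (rounded to 2 digits), 247 in liver and 210 in WAT, TLS against time-0 gave 408, 457 and 373. The sex difference gave 1331 in cortex, 16 in kidney, 10 in liver and 2.2e+02 in WAT (rounded likewise). With limma voom and quality weights, TLS against control gave 398 in kidney, 1184 in liver and 0 in WAT, control against time-0 2515, 1397 and 726, TLS against time-0 2269, 531 and 394, and the sex difference 1781 in cortex, 2054 in kidney, 14 in liver and 2 in WAT. Without the sex covariate the 3 contrasts gave 7, 12 and 20 in kidney and 154, 39 and 89 in liver, and TLS against control 0 in WAT. With only the 2 groups compared they gave 12, 139 and 43 in kidney, 64, 349 and 55 in liver and 0, 69 and 11 in WAT. With sex crossed with treatment, TLS against control gave 1519 in cortex, control against time-0 76 in kidney and TLS against time-0 96 in WAT. Without the low-count filter, control against time-0 gave 11 and TLS against time-0 8 in WAT, the sex difference 1 in kidney and 191 in liver, and the tissue difference 236 against 494. With the animal as a replicate block the tissue difference gave 263, and 473 in limma without the block. RLE size factors gave 1 for the sex difference in WAT. Exchanging the letters of kidney time-0 animals 4 and 5 gave 7, 14 and 48 for the 3 contrasts, but Xist and Y-linked genes fitted the original letters, so this says nothing about stability. Without TLS animal A5DA, TLS against control gave 451 in cortex and 3 in WAT, TLS against time-0 79 in WAT, the sex difference 4 in kidney and 3 in liver, and the tissue difference 802. Without A5DA and B4B9, TLS against control gave 339 in cortex and 2 in WAT, TLS against time-0 70 in kidney, and the sex difference 1492 in cortex and 5 in liver. Without TLS animal B51B liver gave 137 and 100 for TLS against control and against time-0. Without time-0 animal 6, WAT gave 62 for control against time-0, 186 for TLS against time-0 and 2 for the sex difference, and without the libraries high in muscle genes 0, 6 and 6 for the 3 contrasts. In F libraries alone TLS against control gave 2 in cortex, 2 in liver and 0 in WAT, control against time-0 1964 in kidney, 1 in liver and 47 in WAT, and TLS against time-0 198, 9 and 1. In M libraries alone the 3 contrasts gave 3404, 1160 and 2971 in cortex, 0, 0 and 4 in kidney, 48, 6 and 22 in liver and 0, 0 and 0 in WAT. With the nuclear RNA share as a covariate, TLS against control gave 2 in cortex, 22 in kidney, 449 in liver and 0 in WAT. Control against time-0 gave 83 in kidney, 117 in liver and 16 in WAT, TLS against time-0 807, 36, 321 and 116, and the sex difference 21 in cortex; with the neighbouring-region score the last was 3. The relation of the 3-month change to the TLS effect was 0.00826 in cortex, -0.0796 in kidney, -0.279 in liver and -0.157 in WAT. With all control libraries in both differences it was -0.138, -0.372, -0.506 and -0.428, in F libraries alone -0.0136 in cortex and -0.325 in kidney, and in M libraries alone -0.291 and 0.0587. Of the lists, 47 were called for TLS against control and 38 for control against time-0; an estimated correlation gave 0 and 0 and fry 12 and 7. Lists whose direction reversed, with a call under either setting, are given here as camera adjusted p. Each pair of values thus stands for opposite directions. Lists that gained or lost a call in the same direction are not given. For TLS against control in cortex, neighbouring-region markers went from 0.0974 to 0.000757 in M alone. In kidney the interferon response went from 0.000529 to 0.0734 without A5DA and B4B9, macrophage markers from 0.709 to 0.00189 without A5DA, 1.26e-05 without both and 0.00226 in F alone, fatty acid oxidation from 0.000208 to 0.2 in M alone and female-biased genes from 0.0293 to 0.406 in M alone. In liver the interferon response went from 0.54 to 0.00502 without both, and fatty acid oxidation from 0.704 to 0.00456 without both and 0.000705 in F alone. In WAT macrophage markers went from 0.476 to 0.0108 without A5DA and 0.024 without both, and in F alone lymphocyte markers from 0.0462 to 0.25, cell cycle from 0.0118 to 0.653, oxidative phosphorylation from 0.13 to 8.55e-06 and adipocyte identity from 0.0444 to 0.0116. For control against time-0 in M alone, mitochondrially encoded genes went from 0.373 to 0.000437 and fatty acid oxidation from 0.00146 to 0.232 in kidney, and cell cycle from 0.653 to 0.0098 in WAT. In F alone, glucocorticoid response genes went from 0.94 to 0.0391 in liver, and mitochondrially encoded genes from 0.513 to 0.00155 and adipocyte identity from 0.826 to 0.0143 in WAT. Leaving out 1 library at a time, TLS against control ran from 333 to 1374 in cortex, 16 to 35 in kidney, 84 to 803 in liver and 0 to 3 in WAT. The sex difference ran from 355 to 1287, 0 to 4, 0 to 3 and 0 to 1, and the tissue difference from 182 to 1088.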

Other observations

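The differences between M and F animals within each group were counted only after the sex difference in cortex was seen. In kidney, the tissue with the most, 4371 autosomal genes differed between M and F controls, 2459 higher and 1912 lower in M, against 3528 in TLS animals (2026 and 1502) and 1515 at time-0 (822 and 693). In liver the numbers were close to each other, 282 in controls, 223 after TLS and 225 at time-0. In WAT there were 383 in controls, 354 at time-0 and 1015 after TLS (434 higher and 581 lower in M). The WAT libraries of the F TLS animals B51B and B4B9 are high in muscle genes (Ckm at 843 and 121 CPM against a control median of 0.0921). That of the M TLS animal A5DA stands apart on the adipocyte score (-1.9). The count without them was not taken, so the rise is not read as an effect of TLS. In cortex there were 1811 in controls, 51 after TLS and 4 at time-0, each from 4 M and 4 F animals by edgeR.

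The redrawn groupings were fixed beforehand except those for TLS against control in WAT, which were added after the result was seen, as was the reading of those for the sex difference, and all were drawn within sex. For TLS against control, only the real grouping, 1 of 40, reached the count in cortex (899 calls, highest other split 262), kidney (37 against 1) and liver (265 against 1). In WAT 2 of 40 reached 1 (highest other 1), so chance is not excluded there. A share of 1 of 40 is the lowest that 40 splits can give, and no allowance was made for the number of contrasts. Such counts were thus rare among the splits, which does not fully exclude chance. The splits cannot tell TLS apart from library order either. For control against time-0, 1 of 40 reached the count in cortex (3527 against 114), kidney (50 against 0), liver (72 against 0) and WAT (27 against 12). For TLS against time-0, 1 of 40 reached the count in cortex (5934 against 0), kidney (109 against 0) and WAT (38 against 15). In liver 3 of 40 reached 182 (highest other 235), so chance is not excluded there. For the sex difference the splits do not decide. The count was reached by 2 of 40 in cortex (844, highest other 1519) and 4 of 40 in liver (1, highest other 226). In kidney and WAT the real count is 0, which all 40 of 40 reach whatever the data (highest other 41 and 25). The splits with 1519, 226 and 41 calls set F TLS and M control animals against the rest, which turns the contrast into the TLS effect itself, and TLS against control with sex crossed with treatment gave the same 1519, 226 and 41. Other splits hold part of that effect; the next highest in cortex gave 3. The WAT split with 25 calls puts B51B, B4B9 and A123, which are high in muscle genes, in the same group. Whether these libraries give its calls was not tested. The tissue difference was reached by 1 of 25 (494, highest other 340). The counts of called lists were reached by 43 of 100 splits for TLS against control (47, highest other 63) and 10 of 100 for control against time-0 (38, highest other 42), so chance cannot be excluded for either count.

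For the cortex sex difference, the outcomes for the nuclear RNA share and the neighbouring-region score were written down before their values were seen, but all covariate fits were added after the result was seen, as were the comparison of sizes and errors used to read them and the test of drift. Across genes, the within-group slope on the nuclear RNA share correlated with the sex difference at -0.327, with 0.03 of 1000 shuffles as low, and 21 genes were called with the share as a covariate (18 shared) and 3 with the neighbouring-region score (2 shared). With the choroid plexus score 882 were called (772 shared; median size 0.59 to 0.596) and with log2 total counts 1250 (823 shared; 0.626). The nuclear RNA share and the neighbouring-region score met the outcome written for each. With them the median size of the difference moved only from 0.59 to 0.51 and 0.491, while its SE grew from 0.145 to 0.197 and 0.185, so both RNA composition and dissection could be the cause and neither is settled. Had TLS acted on M animals alone, with M and F otherwise alike, more genes would differ between them in TLS than control libraries. Instead, 51 autosomal genes differed in TLS libraries and 1811 in controls. This control difference is itself part of the tested contrast. RNA composition or dissection in the M control libraries could also give it, so such an effect is not excluded in the animals. A gradual drift along the library numbers is excluded. The numbers of M and F controls alternate, and in the mean of the 844 genes, signed by the difference, the drift over the gap between them was -0.00936 ± 0.0104 (SE, n = 8) against an M to F difference of -0.557. M and F libraries hold fixed places that repeat along the numbers, and an effect of place that differs between TLS and control libraries was not tested. A change over 3 months that differs by sex in controls was not tested either.

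The tests on A5DA and on muscle genes in WAT were chosen after the results were seen. Thinned to the lowest liver total, A5DA kept an acute phase score of 4.84 with the next library at 0.59, so depth is excluded. Its deviations correlated between tissues at a mean of 0.267, with the next animal at 0.183, so the state belongs to the animal and not to 1 library. Whether it is illness, injury or a response to TLS cannot be told from 1 animal. Without it TLS against control gave 451 calls in cortex and 394 in liver.

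The muscle tests in WAT were also chosen after the result was seen. Levels of 12 muscle genes in the TLS animals B51B and B4B9 correlated at 0.832 (Spearman, one-sided permutation p = 0.00078), with Acta1 at 1600 and 291 CPM against a control median of 45.6, Ckm at 843 and 121 against 0.0921 and Tnnt3 at 884 and 136 against 1.61. These libraries were picked for high muscle genes, and the genes would rank alike also if the fat tissue expressed them, so muscle carried over with the tissue could be the source but is not settled. Only 3 of 8 TLS libraries lay above the highest control library, A123, and also 3 with A123 left out, so an effect of this size on every animal is excluded and a smaller shift is not. Without the libraries high in muscle genes, WAT gave 6 calls for TLS against time-0 in place of 38. That fit left out TLS animals B51B, B4B9 and B23B and control animal A123, all F. The loss of replicates could lower the count as well, so the fall is not read as the share due to muscle.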
